A study of Caenorhabditis elegans with 8 samples.

How the data were processed

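The series holds 8 Agilent oligonucleotide arrays with 2 colours, each hybridised with total RNA of C. elegans from a pair of strains. The Cy3 channel held a double mutant, daf-2 xbp-1(zc12), and the Cy5 channel held its matched daf-2 single mutant. In 4 arrays the daf-2 allele was e1368 and in 4 it was e1370, and the submitters describe the sets as biological replicates. Per the labels, animals were synchronised from bleached eggs, grown at 20 °C and collected as adults of day 1, which took 72 hours for e1368 and 96 hours for e1370. RNA was extracted with Trizol and labelled with the Agilent QuickAmp kit, per the labels' protocols.

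The authors deposited the scanner output of each array, in which foreground and background values are spot intensities on a linear scale from Agilent Feature Extraction 9.5.3.1, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 computed by that software, which the authors deposited unchanged and which served here only to check directions. The deposited series table holds 1 column per array of log2 values, which proved to be log2(Cy5 / Cy3). Its columns correlated with the scanner's ratio at r from 0.969 to 0.991, with slopes from 0.909 to 0.999, which set its direction and scale. In the deposited direction, Cy5 over Cy3, its column medians were -0.0436, -0.0999, 0.0414 and 0.0606 for e1368 replicates 1 to 4, and 0.0261, 0.167, 0.108 and 0.0787 for e1370 replicates 1 to 4. How that table was centred and filtered is not given in the sources used here. The labels state the same dye orientation for all arrays, so a dye effect specific to a gene is not cancelled in any comparison of double with single mutants. In the comparison of the effect between backgrounds it would cancel only if it were equal in both, which was not tested.

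Each array carried 42964 spots of 20401 probes besides controls. The median intensities of Cy3 and Cy5 over the e1368 arrays were 568 and 459, 215 and 364, 316 and 422, and 165 and 240 for replicates 1 to 4. Over the e1370 arrays they were 298 and 437, 498 and 315, 755 and 452, and 364 and 323. Between 75.3% and 97.4% of probes were well above background in a channel. The number of arrays, 4 per background, limits the precision of every value.

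Mean foreground and median background intensities were corrected with normexp and an offset of 50, and log ratios were normalised by loess within each array with control spots at weight 0. The offset draws the ratios of dim genes towards zero, so their folds depend on the background correction. No scaling between arrays was applied. Control spots and spots marked as outliers were left out, and replicate spots of a probe were averaged. A probe was kept if it was well above background in at least 4 of the 16 channel measurements, which left 19144 probes. Each gene was read by its brightest probe, and 18222 genes were tested. Of 801 genes with more than 1 probe, 0 had probes called in opposite directions by limma for the mean of both backgrounds, and 12 of the 56 such genes called by the brightest probe had another probe of opposite sign. Probe names were updated through the reference gene table of assembly WBcel235, which was used for names and for the order of neighbouring genes. In it 19057 probes matched by locus tag and 1344 did not. Of the tested genes, 17110 have an entry there, 473 are known by a probe ID alone, and 647 are read by a probe that the array design assigns to several genes, called shared below. Probe positions are those in the array files, and their genome build is not given in the sources used here.

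The log2 ratios of double over single mutant were fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3 with statmod 1.5.0), with a mean per background over all 8 arrays and one shared estimate of the spread. Positive values mean more transcript in the double mutant. The contrasts were the mean of both backgrounds, e1368, e1370 and the difference, e1370 minus e1368. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p in the text is from limma. SE is that of the limma estimate, SD is that of the 4 arrays of a background, and fold is the double mutant's level over the single mutant's. Gene lists were tested with camera, with a preset correlation between genes of 0.01 and adjustment over 34 lists in each contrast. None of the camera calls, in any contrast, held when the correlation was estimated from the arrays instead, and the adjusted p so obtained stands beside most of the lists described in the text. The rotation test fry was run beside it. Where a probe was not well above background in a genotype on all 4 arrays of a background, only a bound could be set, on channel means after loess and Aquantile scaling, which stay open to dye bias.

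The groups, the tests, the 34 gene lists, the alternatives and the named-gene rule were set before the data were examined. The named-gene rule takes the 8 largest rises and 8 largest falls among called genes with the same sign on every array of a contrast, for the mean and for each background, and the 5 largest each way for the difference. It adds up to 4 members of each list that held a call or was called by camera in any contrast, by smallest p for the mean, or for the difference where camera called the list there, and xbp-1, ire-1, pek-1, atf-6, hsp-3, hsp-4, dnj-27, sod-3, daf-2 and daf-16. Genes outside the rule are said to be chosen after their values were seen. A secondary comparison set the Cy5 channels of the single mutants against each other, e1370 against e1368, after loess and Aquantile scaling.

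Alternatives covered the background correction, the scanner's processed signals, median centring, Aquantile scaling, the filter on dim probes, the mean of a gene's probes, a trended and robust variance, array quality weights, each background fitted alone, the replicate number as a block, the deposited log2 table, a test against a fold of 1.2, an adjusted p under 0.01, and each array left out in turn. The median log2 ratio of sperm genes as a covariate, and all counts without sperm, collagen and moulting genes, were added after seeing the data. A range of adjusted p over alternatives in the text leaves out the fit with the replicate block. All e1368 arrays were on slide 1 and in scan 1, and all e1370 arrays were on slide 2 and in scan 2. Slide and scan could therefore not be used as a block, and slide, scan, harvest time and daf-2 allele cannot be told apart.

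The fits were tested on simulated data for 18222 genes, with normal values drawn independently for each gene at its moderated limma spread, and 50 genes changed at each fold. The changes were set in both backgrounds, or in e1370 alone for the difference. Correlation between genes was not simulated, so the shares say nothing about it. Each simulated gene had the same spread on all 8 arrays. On the real arrays the SD of the log2 ratios over genes ran from 0.30 (e1368 replicate 1) to 0.74 (e1370 replicate 2). The shares and false calls may therefore not carry over to these data. For the mean, 36% of genes changed 1.2-fold, 74% of those changed 1.5-fold and 90% of those changed 2-fold were recovered, with 6 false calls. For e1368 the shares were 0%, 52% and 84% with 5 false calls, for e1370 2%, 56% and 80% with 2, and for the difference 0%, 38% and 62% with 2. At 4-fold the shares were 100%, 100%, 98% and 96% in that order. For the mean, the list test called the 1 shifted list and 0 of the other lists among 20 simulated lists of 30 genes, with a shift of 0.5 on the log2 scale.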

Results

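The arrays compared C. elegans strains with and without the mutation xbp-1(zc12), each carrying a reduced-function allele of daf-2. daf-2 encodes the insulin/IGF-1 receptor of the worm, and xbp-1 encodes the bZIP transcription factor of the IRE-1 branch of the unfolded protein response in the endoplasmic reticulum (ER). The question was which transcripts differ between a daf-2 mutant and the matching daf-2 xbp-1 double mutant. It was asked in 2 daf-2 backgrounds, e1368 and e1370, with 4 arrays each, and 18222 genes were tested. Log ratios are log2 of the double mutant over the single mutant. Arrays of e1368 correlated with each other over all genes at r from -0.16 to 0.613, and arrays of e1370 at r from 0 to 0.907. Across backgrounds some arrays correlated below zero, the lowest being e1368 replicate 2 with e1370 replicate 4 (r = -0.608) and e1368 replicate 1 with e1370 replicate 2 (r = -0.549). The labels state the dyes, so the directions were kept.

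The xbp-1 transcript was lower in the double mutants. Its log2 ratio (R74.3, probe at III:4195255-4195314) was -0.73 (SE 0.131, 8 arrays) over both backgrounds, a level 0.602 times that of the single mutants, with an adjusted p of 0.0246. It was below zero on all 8 arrays, from -1.502 to -0.228. zc12 is a point allele, so this probe reads transcript level and does not check the genotype. The call was lost without e1368 replicate 1 (adjusted p = 0.0589), 2 (0.077) or 3 (0.0583) or e1370 replicate 3 (0.0759), within a range of 0.00304 to 0.115 over the alternatives.

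Most genes of the unfolded protein response did not pass the test in the mean of both backgrounds. The log2 ratios of the sensors were -0.07 for ire-1 (adjusted p = 0.576), -0.17 for pek-1 (0.315) and -0.01 for atf-6 (0.964), the last turning to 0.013 with median centring. The BiP chaperones hsp-3 and hsp-4 gave -0.07 (adjusted p = 0.741) and 0.05 (0.811), hsp-4 turning to -0.184 with median centring, and the ER thioredoxin-fold gene dnj-27 gave 0.13 (0.306). The list of 11 sensors and regulators does not hold xbp-1 itself. In it 1 gene fell, ckb-2, a choline kinase gene and not a sensor, and adjusted over the list alone 1 rose and 2 fell. The list median was 0.039, its mean -0.051 and its camera test pointed down (adjusted p = 0.604). Of 21 genes of ER-associated degradation 1 fell, hrdl-1, with a log2 ratio of -0.47 (adjusted p = 0.0169), and adjusted over the list alone 1 rose and 2 fell. Without e1370 replicate 3 the hrdl-1 adjusted p was 0.0549, in a range of 0.00426 to 0.113. Of 27 ER chaperones and folding enzymes 4 fell, or 6 adjusted over the list alone. These were dnj-28 at -0.57 (SE 0.0894, adjusted p = 0.0171), ero-1 at -0.41 (SE 0.0868, 0.0376), pdi-6 at -0.40 (SE 0.0812, 0.0357) and enpl-1, the GRP94 gene, at -0.15 (SE 0.0271, 0.0241), each chosen after its values were seen. Each lost its call without some single arrays. For dnj-28 these were e1368 replicate 2 (adjusted p = 0.0602) and e1370 replicates 2 (0.05) and 3 (0.0582), range 0.0034 to 0.122. For pdi-6 they were e1368 replicates 1 (0.0726), 2 (0.0894) and 4 (0.0659) and e1370 replicates 1 (0.0572) and 3 (0.0958), range 0.00615 to 0.0958. For ero-1 they were e1368 replicates 2 (0.0878), 3 (0.0838) and 4 (0.0864) and e1370 replicates 2 (0.0971) and 3 (0.0744), range 0.025 to 0.261. For enpl-1 they were e1368 replicates 1 (0.0594), 2 (0.0775), 3 (0.0506) and 4 (0.0616) and e1370 replicates 2 (0.0651) and 3 (0.0625), range 0.0092 to 0.232. Camera did not call the ER chaperone list in the mean (adjusted p = 0.0528). Outside the unfolded protein response, limma called none of sod-3 at 0.24 (adjusted p = 0.304), daf-2 at 0.13 (0.108) and daf-16 at 0.19 (0.369) in the mean. The daf-2 value passed under some alternatives (range 0.0278 to 0.577).

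Over both backgrounds the largest fall was that of argk-1, an arginine kinase gene (F44G3.2, probe at V:16108208-16108267). Its level in the double mutants was 0.0827 times that in the single mutants, with a log2 ratio of -3.60 (SE 0.187, adjusted p = 0.000221). In the e1370 double mutant it was well above background on 2 of 4 arrays, and its log2 ratio was -5.60 with the scanner's processed signals, so the size of the fall depends on the background correction. ckb-2 (B0285.9, III:4370008-4370067) fell to 0.324 times, with a log2 ratio of -1.63 (SE 0.0615, adjusted p = 7.66e-05). ule-3 (D1054.11, V:10797372-10797431) fell to 0.398 times at -1.33 (SE 0.0918, 0.00077), and the C-type lectin gene clec-223 (C03E10.5, V:11280595-11280654) to 0.441 times at -1.18 (SE 0.0739, 0.000581). Among the rises, the C-type lectin genes clec-145 (Y48E1B.16, II:13588947-13589006) and clec-220 (D1054.7, V:10784066-10784171) reached 2.32 and 2.14 times. Their log2 ratios were 1.21 (SE 0.0948, adjusted p = 0.00129) and 1.1 (SE 0.107, 0.00366), and clec-220, well above background in the single mutants on 3 of 4 e1368 and 2 of 4 e1370 arrays, was at 2.46 with the processed signals. In all, 1126 genes passed, 505 higher and 621 lower in the double mutants, and 763 of them had one sign on every array. With the processed signals 286 were higher and 559 lower, and with median centring 175 and 239. At least 2-fold changes were called for 58 genes, 41 higher and 17 lower. The count rested on single arrays: it was 528, 253, 561 and 446 without e1368 replicates 1 to 4, and 381, 310 and 2060 without e1370 replicates 2, 3 and 4.

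**Figure D1:**
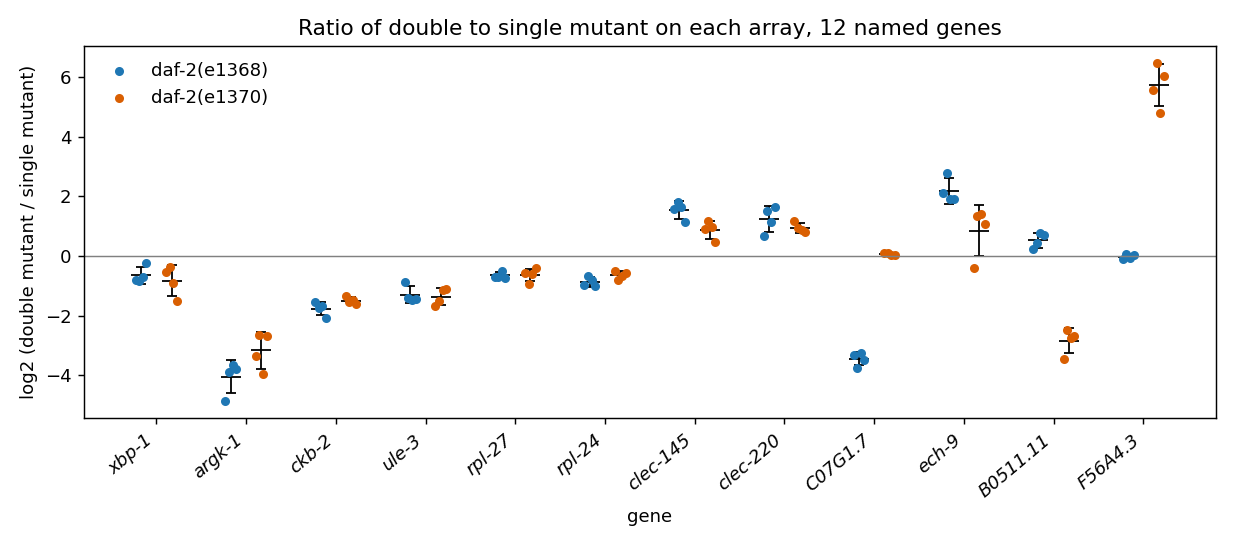
Log2 ratio of double over single mutant on each array (points) for 12 genes, with the mean of the 4 arrays of a background and its SD as bars. argk-1, ckb-2, ule-3, rpl-27 and rpl-24 lay below zero on all 8 arrays and clec-145 and clec-220 above it, while C07G1.7 fell in e1368 and B0511.11 in e1370, and F56A4.3 rose in e1370.

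Of 75 cytosolic ribosomal protein genes, 21 fell and 0 rose by limma in the mean of both backgrounds (34 had an unadjusted p under 0.05), and adjusted over the list alone 28 fell and 1 rose. rpl-27A (Y37E3.8, I:2069692-2069751) fell to 0.527 times at -0.92 (SE 0.0472, adjusted p = 0.000221), rpl-36A to 0.629 times at -0.67 (SE 0.0605, 0.00293) and rpl-27 to 0.642 times at -0.64 (SE 0.0585, 0.00303). The list median was -0.20 (camera adjusted p = 4.77e-08, and adjusted p = 0.726 with an estimated correlation), and the call was lost with the scanner's processed signals (adjusted p = 0.0585) and with the deposited log2 table (0.381), in a range of 6.2e-34 to 0.381. Camera called 12 of the 34 lists in the mean, 7 up and 5 down, and each had an adjusted p of 0.726 with an estimated correlation; fry called 0 of 34. Of 163 collagens 25 rose and 5 fell (68 and 13 adjusted over the list alone, median 0.31). Of 36 moulting genes 6 rose and 2 fell (20 and 3 adjusted over the list alone, median 0.24). These counts rested on single arrays: 11 ribosomal protein genes fell without e1368 replicate 2 and 12 without e1370 replicate 3. Collagens that rose numbered 7, 5, 5 and 5 without e1368 replicates 1 to 4, 55, 8 and 3 without e1370 replicates 1 to 3, and moulting genes that rose 2, 1, 1 and 1 and 10, 6 and 2. The shift differed between the backgrounds for the moulting genes (median difference 0.31, camera adjusted p = 4.03e-06, and adjusted p = 0.611 with an estimated correlation) and for the collagens, as given with that comparison.

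In the e1368 background, C07G1.7 (IV:8211180-8211239) and ZK177.9 (II:5517247-5517306) fell on all 4 arrays, to 0.0919 and 0.314 times the single mutant's level. Their log2 ratios were -3.44 ± 0.216 (SD, n = 4; limma adjusted p = 3.17e-06) and -1.67 ± 0.117 (2.81e-05), and they were well above background on 3 and 2 of 4 arrays in the e1368 double mutant and on 0 in the e1370 strains. With the processed signals the log2 ratios were -5.19 and -4.37, so the sizes of these falls depend on the background correction. In log2 levels, the e1368 single mutant stood apart from the other genotypes for C07G1.7 (10.38) and ZK177.9 (8.11). Their levels were 6.94 and 6.43 in the e1368 double mutant. In the e1370 single mutant, on another slide, they were 6.24 and 6.19. Whether these falls come from the e1368 single strain or from xbp-1(zc12) was not tested. argk-1 fell to 0.0608 times at -4.04 ± 0.563 (adjusted p = 0.00197; -5.58 with the processed signals) and ckb-2 to 0.295 times at -1.76 ± 0.229 (0.000301); fitted on the e1368 arrays alone each had an adjusted p of 0.0532, in ranges of 4.53e-07 to 0.0532 and 6.47e-05 to 0.0532. The largest rises were ech-9, an enoyl-CoA hydratase gene (F01G10.3, IV:10233539-10233598), at 4.54 times, and the UDP-glucuronosyltransferase gene ugt-18 (ZC443.5, V:12825108-12825167), at 3.76 times. Their log2 ratios were 2.18 ± 0.427 (adjusted p = 0.0362) and 1.91 ± 0.184 (0.00978), the latter 3.30 with the processed signals. The ech-9 call was lost without e1368 replicates 1 to 4 (adjusted p = 0.163, 0.172, 0.0848 and 0.125) or e1370 replicates 2 to 4 (0.0642, 0.0763 and 0.0522), range 0.0069 to 0.172. That of ugt-18 was lost without e1368 replicates 2 to 4 (0.0851, 0.0581 and 0.0638), range 0.000491 to 0.0851. In all, 101 genes passed, 35 higher and 66 lower, and 20 of them at least 2-fold (4 higher, 16 lower). With median centring 5 were higher and 53 lower, with the processed signals 11 and 33, and the e1368 arrays alone gave 5 genes. The count was 22, 12, 20 and 25 without e1368 replicates 1 to 4, and 63, 42 and 31 without e1370 replicates 1 to 3.

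In e1368 the median of the ER chaperones and folding enzymes was -0.21 over 27 genes, with medians per array of -0.15, -0.193, -0.205 and -0.17. Camera gave an adjusted p of 0.00175 (adjusted p = 0.348 with an estimated correlation), and fry an adjusted p of 0.0384. By limma over all genes 0 members passed, 12 had an unadjusted p under 0.05, and adjusted over the list alone 6 fell. Of 75 ribosomal protein genes 5 fell, rpl-27A, rpl-24, rpl-27, rpl-36A and rps-12, the last chosen after its values were seen, and 19 fell and 1 rose adjusted over the list alone. Without single arrays 2 to 4 fell, and 2 fell without any e1368 replicate or e1370 replicate 3. The median was -0.18 (camera adjusted p = 9.78e-05, and adjusted p = 0.942 with an estimated correlation). That call was lost without e1368 replicate 1 (adjusted p = 0.292), with the processed signals (0.114) and with the deposited log2 table (0.778), in a range of 9.89e-27 to 0.778. Camera called 10 of 34 lists in e1368, 4 up and 6 down, and fry called the ER chaperones alone. Of 163 collagens 3 fell, col-84, col-106 and col-8, each chosen after its values were seen, and adjusted over the list alone 1 rose and 8 fell. By limma 3 collagens fell without e1368 replicate 4 and 0 without any other array, and the col-84 call was lost without e1368 replicate 4 too (adjusted p = 0.162, range 0.0287 to 0.168). Sperm genes had a median of -0.29 with 0 of 57 called by limma (2 at an unadjusted p under 0.05), and the medians per array were -0.948, -1.871, 0.596 and 1.005.

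In the e1370 background, F56A4.3 (V:2455848-2455907) was 53 times as abundant in the double mutant, the largest rise, at a log2 ratio of 5.73 ± 0.71 (SD, n = 4; limma adjusted p = 7.56e-05). The beta-galactosidase gene bgal-2 (H22K11.2, X:6787149-6787208) rose 8.88 times at 3.15 ± 0.326 (9.53e-05) and the collagen gene col-137 (IV:16601473-16601532) 11.3 times at 3.50 ± 0.938 (0.00541). For col-137 the adjusted p was 0.112 on the e1370 arrays alone and 0.131 with the sperm covariate, in a range of 0.000861 to 0.131, and the covariate brought the ratio to 2.24. The neighbours B0511.11 (I:10656716-10656775) and the F-box gene fbxa-125 (I:10655758-10655817) fell to 0.14 and 0.162 times, at -2.84 ± 0.413 (adjusted p = 0.000259) and -2.63 ± 0.307 (0.000131), the latter -3.68 with the deposited log2 table. Their neighbour tag-344 fell too, at -2.28 (adjusted p = 0.000353, range 3.39e-05 to 0.0591). F56A4.3 also lies in a block of neighbouring genes with higher ratios in e1370, and such blocks are taken up in the closing section. H37A05.2 (V:13632446-13632505) fell to 0.172 times at -2.54 ± 0.207 (4.02e-05). In log2 levels, the e1370 single mutant lay furthest from the other genotypes for bgal-2 (8.29), B0511.11 (12.67), fbxa-125 (9.67) and H37A05.2 (10.44). Their levels were 11.44, 9.83, 7.04 and 7.9 in the e1370 double mutant. In the e1368 single mutant, on another slide, they were 11.54, 10.4, 6.76 and 7.88. Whether these ratios come from the e1370 single strain or from xbp-1(zc12) was not tested. In all, 1167 genes passed, 642 higher and 525 lower, and 307 of them at least 2-fold (270 higher, 37 lower). The split depended on the scaling, being 1422 higher and 279 lower with median centring, and the count was 2806 with the processed signals, 2940 with the deposited log2 table and 14 on the e1370 arrays alone. The count lay between 470 and 728 without each of e1368 replicates 1 to 4, and was 2232, 244 and 112 without e1370 replicates 1, 2 and 3.

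Of 57 sperm genes, major sperm protein genes among them, 26 rose in the e1370 double mutant (51 adjusted over the list alone), with a median of 2.82 and medians per array of 0.464, 4.199, 3.254 and 3.217. The 26 calls lay close to the threshold: by limma 51 sperm genes passed without e1370 replicate 1 and 0 without any other single array, though 51 had an unadjusted p under 0.05 with all arrays. 21 of these 57 genes are read by shared probes. Of 163 collagens 55 rose and 1 fell (85 and 2 adjusted over the list alone, median 0.56). Of 36 moulting genes 15 rose and 1 fell, cut-1, chosen after its values were seen (21 and 2 adjusted over the list alone, median 0.34). Of 6 vitellogenins, the yolk protein genes, 1 fell, vit-5, read by a shared probe, and adjusted over the list alone 5 fell; its log2 ratio was -0.68 (adjusted p = 0.0489) and the list median -0.64. Collagens that rose numbered 24 and 9 without e1370 replicates 2 and 3, and 35 to 38 without e1370 replicate 4 or e1368 replicates 1 to 3. Moulting genes that rose numbered 9, 7 and 8 without e1368 replicates 1 to 3 and 8, 2 and 7 without e1370 replicates 2 to 4, and 5 vitellogenins fell without e1368 replicate 4 and 0 without any other array. Each of these 4 lists was called by camera, with an adjusted p of 1.24e-19, 5.08e-16, 1.65e-06 and 0.000892 in that order (each with adjusted p = 0.71 with an estimated correlation). fry called the moulting genes (adjusted p = 0.018) and the collagens (0.0359), and gave 0.0646 for the sperm genes and 0.0686 for the vitellogenins. Of 26 abu and related genes, named for their activation when the unfolded protein response is blocked, 4 rose, or 13 adjusted over the list alone. These were abu-12 and abu-13 with abu-10 and abu-14, the latter pair chosen after their values were seen. With the sperm covariate abu-10 and abu-14 had log2 ratios of 0.193 and 0.183, against 0.445 and 0.781, and abu-10 had 2.32 with the deposited log2 table. Of the list 2, 2, 3 and 2 rose without e1368 replicates 1 to 4 and 8, 1, 0 and 3 without e1370 replicates 1 to 4. The list median was 0.27 (camera adjusted p = 3.29e-05, and adjusted p = 0.71 with an estimated correlation; fry 0.0424). Of 75 ribosomal protein genes 13 fell (21 fell and 1 rose adjusted over the list alone, median -0.23, camera adjusted p = 9.07e-08, and adjusted p = 0.812 with an estimated correlation), and 7 and 4 fell without e1370 replicates 2 and 3. Of 32 proteasome subunits 4 fell, pbs-7, pas-2, pas-4 and pas-5, and 4 adjusted over the list alone (median -0.07, camera adjusted p = 0.0285, and adjusted p = 0.71 with an estimated correlation). Of 32 muscle markers 2 rose, tnt-4 and ttn-1, the latter chosen after its values were seen, and 9 adjusted over the list alone (median 0.40, turning to -0.123 with the sperm covariate, camera adjusted p = 2.56e-05, and adjusted p = 0.812 with an estimated correlation). Of 60 neuron markers cat-2 and unc-104 rose and tax-4 fell, unc-104 chosen after its values were seen (2 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0453, and adjusted p = 0.812 with an estimated correlation). The neuron call was lost without e1370 replicate 1 (adjusted p = 0.343) or 4 (0.0596), in a range of 0.000477 to 0.553. Without e1370 replicate 3 the proteasome list had an adjusted p of 0.081, in a range of 3.33e-06 to 0.928, and 2 subunits fell without e1368 replicate 2 and 0 without e1370 replicates 2 or 3. Of the muscle markers 1, 0, 0 and 4 rose without e1368 replicates 1 to 4, 8 without e1370 replicate 1 and 0 without its other replicates, and of the neuron markers at most 1 rose without any single array. Camera called 11 of 34 lists, 7 up and 4 down, and fry 4. Also among the 11 were genes raised by DAF-16, up, and F-box and BTB genes, down (0 lists with an estimated correlation). Of 24 DAF-16 genes 0 were called by limma, and the list's adjusted p ranged from 8.67e-05 to 0.305. Of 413 F-box and BTB genes 4 rose and 16 fell, and 1 fell without e1370 replicate 2 or 3.

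**Figure D2:**
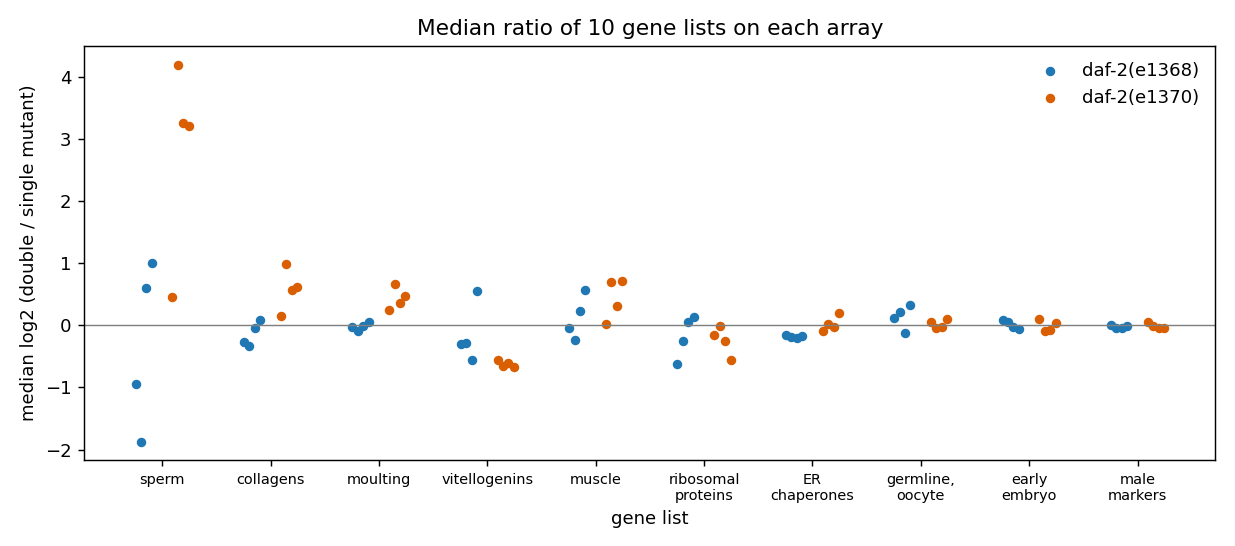
Median log2 ratio of double over single mutant on each array for 10 gene lists, with the arrays of e1368 and e1370 in different colours. The sperm medians ranged from -1.871 to 1.005 in e1368 and from 0.464 to 4.199 in e1370, whereas the ER chaperone medians in e1368 lay between -0.205 and -0.15.

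The effect of xbp-1(zc12) was then compared between the backgrounds, and 85 genes differed, 54 with a higher and 31 with a lower ratio in e1370 than in e1368. With median centring these were 296 and 19, with the processed signals 236 and 134, and 833 and 437 with the deposited log2 table. For C07G1.7, ZK177.9 and a probe without a gene name, which are among the 85, neither strain of a background was well above background on any array (e1370 for the first pair, e1368 for the probe), so a difference of effect is not shown for them. Among the others, the difference was 5.75 for F56A4.3 (adjusted p = 0.000598), which in e1368 lay near the floor and was well above background on 3 and 2 of 4 arrays in the single and double mutant, and 3.33 for bgal-2 (0.000643). It was -3.37 for B0511.11 (0.000937), -2.83 for fbxa-125 (0.000767) and -2.66 for H37A05.2 (0.000179). With the sperm covariate B0511.11 was at -4.02, and with the deposited log2 table fbxa-125 was at -4.25 and H37A05.2 at -3.30. Of the 85, 14 were called without each array in turn, among them the 5 whose values are given. Collagens included 7 genes with a higher ratio in e1370, 63 and 8 without e1370 replicates 1 and 2 and 0 without any other array (72 and 1 lower adjusted over the list alone, median difference 0.64, camera adjusted p = 6.53e-24, and adjusted p = 0.611 with an estimated correlation). Sperm genes had a median difference of 3.19 with 0 of 57 called by limma, 52 at an unadjusted p under 0.05, and 52 called adjusted over the list alone (camera adjusted p = 4.21e-25, and adjusted p = 0.733 with an estimated correlation). Camera called 7 of 34 lists and fry 0. The count of genes was 17, 21, 21 and 24 without e1368 replicates 1 to 4, and 1503, 46, 14 and 35 without e1370 replicates 1 to 4. Because each background lay on a slide and scan of its own and was harvested at a time of its own, the allele cannot be told apart from these.

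Between the called genes of the backgrounds, independent lists would share 1.23 higher and 1.90 lower. Both contrasts used one estimate of the spread per gene, so the lists are not independent and that baseline may be too low. In the data 39 were shared with the same sign, 13 higher and 26 lower. With median centring 3 were higher and 33 lower, and with each background fitted alone 0 were shared by limma (2849 and 5071 genes had an unadjusted p under 0.05 in e1368 and e1370 with all arrays). argk-1, ckb-2, ule-3, clec-223, clec-145, pitr-3 and rpl-27A were among them. 3 genes were called with opposite signs, F07B7.2, which is read by a shared probe, ugt-64, which was chosen after its values were seen, and a probe without a gene name. The ugt-64 call in e1368 was lost without e1368 replicates 1 to 3 (adjusted p = 0.0695, 0.0786 and 0.0581, range 0.00306 to 0.39). Its call in e1370 was lost without e1368 replicates 1 to 3 (0.0649, 0.0646 and 0.0612) or e1370 replicates 2 to 4 (0.111, 0.13 and 0.0502), range 0.00533 to 0.354. That of F07B7.2 in e1368 was lost without e1368 replicates 1 (0.0854) and 2 (0.058), range 0.0032 to 0.166. Across all genes the effects in e1368 and e1370 correlated at r = -0.0911, where genes are not independent replicates. Of the e1368 calls, 78.2% had the same sign in e1370, and of the e1370 calls 60.2% had the same sign in e1368. All arrays had one dye orientation, so whether dye effects of single genes contribute to this overlap was not tested. The shared count was 13, 9, 11 and 9 without e1368 replicates 1 to 4, and 16 and 12 without e1370 replicates 2 and 3.

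**Figure D3:**
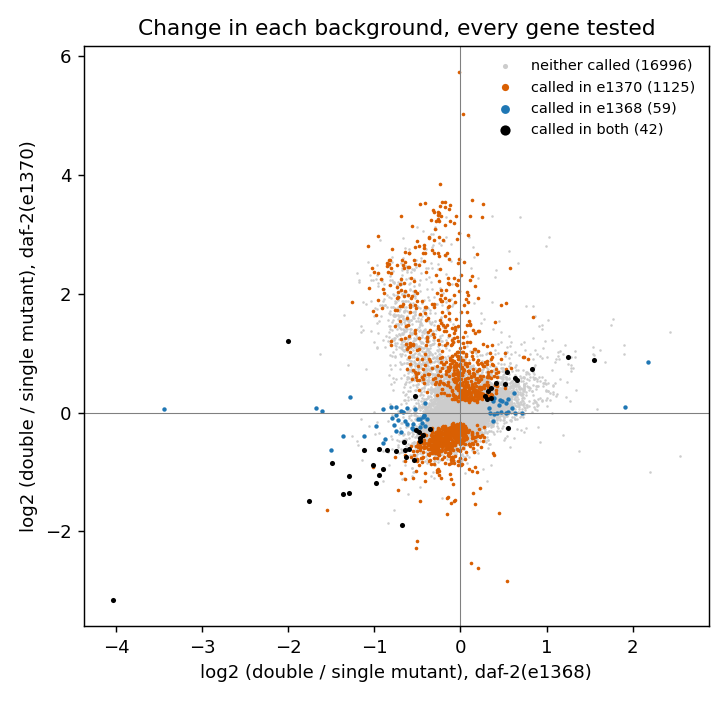
Log2 ratio of double over single mutant in e1368 (x axis) against e1370 (y axis) for each of 18222 genes, coloured by the background in which the gene was called. Genes called in e1370 spread along the y axis, and the effects correlated at -0.0911 across genes.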

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

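Of the tests here, those of chromosome segments, males, a stage difference, slide or scan, a dye offset and a brightness trend were chosen only after the result was seen. The verdicts on males, the stage difference, the dye offset, the brightness trend and gene families were also made more cautious after their values were seen. The reasons were dim markers, a first test on the genes that make the pattern, and values close to a threshold. Random lists without correlation between genes, and lists that hold few of the genes in question, were the others.

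Of 80 genes called for the difference between backgrounds and with a known neighbour order, 21 had a called neighbour of the same sign within 5 genes, in 7 blocks of up to 8 genes, where random draws gave a mean of 1.88 and at most 12 (share 1e-04, the smallest that 10000 draws can give). The blocks include tag-344 with fbxa-125 and B0511.11, and the largest holds F56A4.3. Of the 21, 9 are read by shared probes, and in the largest block only F56A4.3 and srd-61 are not. ZK177.9, for which no difference of effect is shown, makes a block with C17C3.9. Probes shared between genes are argued against as the whole cause, since without them 11 of 64 called genes had such a neighbour (random mean 1.21, at most 10). Without the members of the gene lists 20 of 63 did (random mean 1.33, at most 10), but only 1 of the 21 is in a list, so that test is void and families in clusters stay open. Chromosome segments that differ between the strains, carried along with an allele from another parent strain, are a candidate explanation that would give the 21, as would regulation of neighbouring genes together, which was not tested.

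In e1370, 26 of 57 sperm genes and 55 of 163 collagens rose, 1 collagen and 1 of 6 vitellogenins fell (0 sperm genes passed in limma without any single array but e1370 replicate 1), each list was called by camera only with its preset correlation (adjusted p = 0.71 with an estimated correlation), and the sperm medians of the e1368 arrays went both ways. An exchange of labels or dyes on an array is argued against but not excluded. Of the genes called without an array, at least 78.2% kept their sign on it, except for e1370 replicate 4. There the share was 57.3%, little above an even split. argk-1 lay between -4.873 and -2.637 on all 8. A gene with a dye effect common to all arrays would keep its sign even in an exchange, which limits this test. A stage difference between the populations may give this pattern, but the early embryo list, which is not part of it, had a median of -0.044 in e1370 and was not called, which decides nothing. The test of slide or scan is void, since 0 slides hold both backgrounds, and so neither these nor harvest time can be told apart from the daf-2 allele. Males among the animals are taken up under the other observations, and an effect of xbp-1 itself on germline or cuticle genes stays open and untested.

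The ribosomal protein list was called down by camera with its preset correlation in both backgrounds (adjusted p = 0.942 in e1368 and 0.812 in e1370 with an estimated correlation; the e1368 call was lost without its replicate 1, at 0.292 in a range of 9.89e-27 to 0.778), with medians per array of -0.618, -0.25, 0.062 and 0.143 in e1368 and -0.149, -0.007, -0.251 and -0.564 in e1370, so 2 of the 4 in e1368 lay above zero. For a trend with brightness left by the normalisation, the list median of -0.198 lay at percentile 2.1 of 10000 random lists of like brightness, whose median was -0.082. That percentile is below the bound of 2.5 but close to it. The random lists were drawn gene by gene, so they lack the correlation between members with which the camera call was lost. The test therefore cannot decide on such a trend. The camera call was also lost with the scanner's processed signals (-0.097) and with the deposited log2 table (-0.055). A constant dye offset would give like values on every array, and the SD of the list median over arrays, 0.277 against a median of 0.224 in random lists, lay at percentile 94.4, just under the bound of 95. With 1 dye orientation an offset cannot be told apart from an effect of xbp-1, which was not tested further.

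Single arrays stood apart in 16 of 418 groups of 4 values, where chance gives about 1 in 20, or 20.9. In e1368 replicate 1 ule-3 was at -0.878 (others -1.468 to -1.404). In e1368 replicate 2 fat-7 was at -0.955 (others -0.138 to 0.002). In e1368 replicate 3 rpl-27 was at -0.486 (others -0.723 to -0.692), ptr-4 at -0.098 (0.066 to 0.098), bath-45 at -0.249 (-0.624 to -0.613) and dod-3 at 2.177 (0.32 to 0.498). In e1368 replicate 4 the UDP-glucuronosyltransferases had a median of -0.321 (others -0.065 to -0.043). In e1370 replicate 1 ssp-9 was at 0.328 (others 3.217 to 3.503) and nspd-1 at 0.422 (3.506 to 3.771). In e1370 replicate 2 rpl-27A was at -1.18 (others -0.898 to -0.849), abu-13 at 2.569 (1.056 to 1.194) and atg-4.2 at -0.899 (-0.25 to -0.117). In e1370 replicate 4 F09E10.1 was at -2.688 (others -1.334 to -1.204), sec-23 at 0.384 (0.174 to 0.208), pek-1 at 0.439 (-0.246 to -0.197) and the genes raised by DAF-16 had a median of -0.27 (0.429 to 0.507).

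Effects called as different between the backgrounds, as e1370 minus e1368 on the log2 scale, were positive for F56A4.3 (5.75), C07G1.7 (3.51), lon-3 (3.39), bgal-2 (3.33), rol-6 (3.21), F07B7.2 (3.20), rol-8 (3.02), col-90 (2.84), ZK177.9 (1.75), col-150 (1.66), nlp-34 (1.44), C08F11.7 (0.96) and nas-6 (0.65). They were negative for B0511.11 (-3.37), fbxa-125 (-2.83), H37A05.2 (-2.66), ugt-18 (-1.81), tag-344 (-1.76), cls-3 (-1.66), Y55F3AM.11 (-1.55), ugt-31 (-1.49), Y41C4A.11 (-1.22) and ugt-64 (-0.82). C07G1.7 and ZK177.9 were not well above background on any e1370 array of either strain, so no effect could be measured there and their values do not show a difference of effect. nas-6 was not well above background in the e1370 single mutant (at least 1.59-fold higher in the double mutant) and was so on 2 of 4 arrays of each e1368 strain. F56A4.3 lay near the floor in e1368, on 3 and 2 of 4 arrays well above background in the single and double mutant. Of these genes F56A4.3, C07G1.7, ZK177.9, bgal-2, B0511.11, fbxa-125 and H37A05.2 were called without each array in turn. The call of F07B7.2 was lost without e1370 replicate 3 and that of ugt-64 without it or e1368 replicate 1. The other 14 lost their calls without 4 to 7 of the 8 arrays, e1368 replicate 1 and e1370 replicate 3 among them each time, with a highest adjusted p of 0.0912 to 0.165. ugt-18 was at -3.47 with the deposited log2 table, and lon-3 at 2.21 and rol-6 at 1.92 with the sperm covariate. The list medians differed, by camera with its preset correlation, by 3.194 for sperm genes (adjusted p = 0.733 with an estimated correlation), 0.635 for collagens (0.611), 0.305 for moulting genes (0.611), 0.245 for muscle markers (0.895), 0.115 for abu genes (0.841), 0.09 for ER chaperones (0.611) and -0.501 for vitellogenins (0.841).

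For the mean of both backgrounds, turning the sign of whole arrays gave at least 1126 genes in 1 of 100 patterns of signs, the real one (highest other 259). This is the smallest share that 100 patterns can give, and it argues against chance for the count. A dye effect with the same sign on all arrays would give it too, so this test cannot tell such an effect from that of xbp-1. For the 39 genes called in both it was 1 of 100 (highest other 3), and such a dye effect would give them too. Turning some but not all arrays of a background left 0 calls in that background, so 0 shared genes then follow. The shared count is therefore not a separate test of sharing between the backgrounds. For the 12 lists of the mean chance cannot be excluded (20 of 100, highest other 15). Within a background 8 patterns of signs are too few for a share under 0.05: the real value was 101 genes in e1368 (1 of 8, highest other 0) and 1167 in e1370 (1 of 8, highest other 0), 10 lists in e1368 (4 of 8, highest other 17) and 11 in e1370 (4 of 8, highest other 15). For the difference, 1 of 35 splits of the 8 arrays, the real one, gave as many as 85 genes (highest other 22), which argues against chance but not against slide, scan or harvest time, which follow the same split. Its 7 lists were matched by 32 of 35 splits (highest other 17), so chance cannot be excluded. Why lists were called in the other splits was not tested, and with an estimated correlation 0 lists were called for the difference. For the 3668 genes that differed between the single mutants it was 1 of 35 (highest other 0), which argues against chance but not against slide, scan or harvest time.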

How the results depend on the processing

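The sperm covariate and the counts without sperm, collagen and moulting genes were alternatives chosen only after the result was seen; the other tests here were planned. Counts are given for the mean (1126), e1368 (101), e1370 (1167), the difference (85) and both backgrounds (39), and where a count is not given it stayed within 1.5 times; the cause was not tested unless stated. The scanner's processed signals gave 44 genes in e1368, 2806 in e1370 and 370 for the difference. Median centring gave 414 for the mean, 58 in e1368 (5 higher and 53 lower, against 35 and 66), 1701 in e1370 (1422 and 279, against 642 and 525), 315 for the difference (296 and 19, against 54 and 31) and 13 lists for the difference, against 7; it turned glh-4 to -0.028, phb-2 to -0.086 and the germline list in e1368 to -0.132. Only genes above background in all 16 measurements gave 739 for the mean, 53 in e1368 and 24 in both, fewer genes being tested. A trended, robust variance gave 2064 in e1370, and array quality weights gave 3541, 576, 5488, 2255 and 268. Each background fitted alone, with fewer arrays for the spread, gave 5, 14 and 0 in both by limma (2849 and 5071 genes had an unadjusted p under 0.05 with all arrays). The deposited log2 table gave 2940 in e1370 and 1270 for the difference. The stricter test beyond a fold of 1.2 gave 37, 17, 118, 25 and 7, and an adjusted p under 0.01 gave 146, 19, 128, 15 and 9, with 5 lists in e1368 and 3 for the difference. Camera with an estimated correlation called 0 lists in the mean, 0 in e1368, 0 in e1370 and 0 for the difference, and fry 0, 1, 4 and 0. The replicate block gave 31, 8, 17, 8 and 2, and xbp-1 at -0.733 (adjusted p = 0.137; 0.00304 to 0.115 over the other alternatives); but the numbers do not pair the arrays, since same-numbered arrays deviated with r of -0.032, -0.669, 0.46 and -0.107 and replicates 1 to 4 of e1368 correlated best with numbers 4, 1, 2 and 2. With the sperm covariate the counts were 187, 257, 44, 16 and 7, xbp-1 was -0.782 (adjusted p = 0.115), 13 lists were called for the difference, and lists turned to 0 (sperm, mean, fixed by the covariate's construction), 0.002 (F-box, mean), 0 (cytochromes P450, mean), 0.003 (UDP-glucuronosyltransferases, mean), -0.123 (muscle, e1370), 0.03 (F-box, e1370), 0.02 (proteasome, e1370), -0.37 (muscle, difference) and -0.022 (abu, difference). Without sperm, collagen and moulting genes the counts were 1085, 98, 885, 70 and 37. Leaving out each array in turn gave 253 to 2060 for the mean, 12 to 74 in e1368, 112 to 2232 in e1370, 14 to 1503 for the difference, 9 to 34 in both, xbp-1 from -0.809 to -0.619, and 10 to 16, 7 to 12, 10 to 13 and 6 to 10 lists. The single mutants gave 3668 genes, 2636 to 3683 without each array, 1765 beyond a fold of 1.2 and 2027 at an adjusted p under 0.01, and the double mutants in the Cy3 channel, compared in their place, gave 1851. Of 139 calls of named genes, 21 held under every alternative run; over 2796 checks 733 were lost and 2 reversed, and of 76 results without a call 41 passed under some alternative. Of 40 called list results 10 changed the direction of the test under an alternative, 1 of them that sperm list, and the median of the secretory list in e1368 turned to -0.006 with median centring while its test kept its direction. No block of slide or scan was run, and aquantile scaling leaves log ratios unchanged by construction. Signal over background limits dim genes, as 75.3% to 97.4% of probes were well above it.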

Other observations

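The test of males was chosen only after the result was seen, and the comparison of the single mutants was planned as a secondary one. Between the daf-2 single mutants, 3668 genes differed in the Cy5 channel (limma), 1792 higher and 1876 lower in e1370 than in e1368. Genes with a higher level in e1370 were led by icmt-1 at a log2 difference of 5.35, the nicotinic receptor gene unc-38 at 4.44 and far-3 at 3.70. Those with a lower level were led by the major sperm protein genes msp-64 at -4.77 and msp-32 at -4.32 with nsph-3.1 at -4.44. Of 57 sperm genes 51 were lower (median -3.53) and of 163 collagens 56 were lower and 9 higher (median -0.34). Of 24 genes raised by DAF-16 in daf-2 mutants 14 were higher (median 0.81), among them sod-3, a superoxide dismutase gene, at 1.46 (adjusted p = 0.000691). Of 413 F-box and BTB genes 151 were higher and 16 lower (median 0.29). Camera called these lists with its preset correlation only; with an estimated correlation the adjusted p was 0.37 for the sperm, F-box and DAF-16 lists and 0.482 for the collagens. Slide, scan and harvest time of 72 or 96 hours go with the allele here too.

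In the levels of each genotype, the collagens stood at a median log2 intensity of 10.22 and 10.19 in the e1368 single and double mutants, and at 9.07 and 10.76 in the e1370 single and double mutants. The e1370 single mutant was the lowest of the genotypes for this list, as it was for the sperm genes. Of the 85 genes whose effect differed between backgrounds, 25 had the e1370 single mutant and 28 the e1370 double mutant standing apart from the rest, against 8 and 1 for the e1368 single and double mutants and 23 with none. Among the 25 were bgal-2, B0511.11, fbxa-125 and H37A05.2, and among the 28 was F56A4.3. The 8 include C07G1.7 and ZK177.9, for which no difference of effect is shown. The 85 were picked from the same arrays for a ratio that differs between backgrounds, and 1167 genes were called in e1370 against 101 in e1368. The larger numbers for the e1370 strains may thus follow in part from the selection. On chromosome IV 236 of 2966 genes, or 7.96%, were called in e1370 (Fisher's exact test, two-sided, adjusted p = 0.00623 over 24 tests), and the other 23 tests did not pass. Over all tested genes 1167 of 18222 were called in e1370, and on the other chromosomes 5.34% to 6.78%. The test treats genes as independent, which families that move together are not. It was not repeated with arrays left out, and without e1370 replicate 3 only 112 genes were called in e1370 at all.

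Males among the e1370 double mutants may bring sperm transcripts, and would also bring male genes. The 19 male markers had a median log2 ratio of -0.01 in e1370 (bootstrap SE 0.0228), below the 0.5 set for this hypothesis. However, their median log2 intensity was 6.45 against 8.79 for all genes and only 2 were brighter than the median gene, so the markers were too dim to exclude it. Sperm levels, looked at afterwards, had log2 medians per array of 10.98 to 13.08 in the e1370 double mutant. They were 8.99 to 10.5 in the e1370 single mutant and 11.57 to 14.34 over both e1368 strains. The e1370 double mutant thus held more sperm transcripts than its matched single mutant, but no excess over e1368. The e1368 arrays differ in daf-2 allele, slide, scan and harvest time, so their levels set no bound for e1370. This comparison therefore cannot decide on males, which are not excluded.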
